A study of Homo sapiens with 12 samples.

How the data were processed

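Bulk polyA RNA was sequenced from 12 xenograft tumours of the human breast cancer line MDA-MB-468, 3 from each of 4 subclonal populations, after cells of each population had been placed in the mammary gland of mice. Libraries were made with a stranded kit, per the labels' protocols. The groups (SCP01, SCP03, SCP29 and SCP32) and the tumour letters (A, B and C) come from the sample titles. The submitters' processing notes name cutadapt 1.8 and the genome build GRCh37, without saying what else was run. The aligner, the counting tool and its strand setting, the annotation, and any removal of mouse reads are not given in the sources used here. Reads of the mouse host may therefore be counted in human genes, and reads of overlapping antisense genes may not be separated.

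The table that the authors deposited is named as TPM, but its values are scores on another scale: each column is a constant times the log2 of reads per kilobase relative to library size (RPKM), with values below 0 written as 0. This was read from the values, since 2 to the power of a score divided by the constant, times the gene's length in GENCODE 29, falls on whole reads plus a small prior. A constant and a library size were estimated for each tumour on all low genes of simple structure. They were then refitted on part of these genes, searching only near the first estimate, and checked on the rest. The check is therefore not independent of the first estimate. The constants were between 29.7 and 30.99. In 96 to 175 genes per tumour kept out of the refit, 85.2% to 90.8% of values came within 0.1 of a whole read. With gene lengths shuffled under the same constants it was 17% to 26.1%, and 20% is the share by chance. When the constant was searched anew with shuffled lengths, the score for whole reads reached at most 4.17, against at least 5.89 with the true lengths. The refit changed a constant by at most 0.030%, within its narrow search. Estimated library sizes were 13.67 to 30.54 M reads. Every level given here is the score divided by its constant, which is log2 RPKM, and it stops at a floor of RPKM 1 (log2 of 0). A gene at the floor is listed at 0 and can have any level up to that RPKM. This rests on the values alone, as no source used here states the scale.

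Of 15940 table entries, 1586 without a gene symbol (9.95% of entries, holding 4.38% to 4.77% of each column's score total) and 2 sharing a symbol were left out. Another 1503 named genes were at 0 in all tumours. Genes above the floor in at least 3 of the 12 tumours were tested, which left 12430. Of 14354 symbols, 13715 were found in GENCODE 29. That annotation is on GRCh38, so it was used only for gene lengths, types and order along chromosomes, and no coordinates are given.

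Differences were tested with limma 3.58.1 in R 4.3.3 (linear models of 4 group means, empirical Bayes moderation with a mean-variance trend, two-sided, 8 residual and 4.12 prior degrees of freedom), without a replicate block, because nothing in the labels says that a letter is shared between subclones. All 12 tumours share a spread estimate. The plan assumed TPM and log2(TPM + 1); because the values are scores, log2 RPKM took its place and the test stayed as planned. A moderated F test asked which genes differ among the 4 subclones. Each subclone was then set against the equally weighted mean of the other 3, and each pair of subclones was compared. P-values were adjusted by the Benjamini-Hochberg method over the 12430 genes. A gene counts as different in a comparison at an adjusted p under 0.05 and a log2 difference of at least 1. For members of gene lists, rose and fell mean an adjusted p under 0.05 alone. Many genes of any kind pass that looser rule. Of the 12430 tested genes, 4379 passed it in either direction in SCP01, 2491 in SCP03, 2571 in SCP29 and 6382 in SCP32. Counts of list members that rose or fell are to be read against these numbers, and do not by themselves set a list apart. The share of variance between subclones was tested by an exact permutation over all 15400 partitions of the tumours.

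Pathway, cell state and host cell marker lists, 43 in all, were tested with camera (limma) at a preset correlation of 0.01 where at least 5 members were tested, which held for 37. Adjustment was over all tested lists and the 4 subclones. Camera with an estimated correlation is given beside each call. Genes named in the text are, for each subclone, up to 10 with the highest and 10 with the lowest log2 difference at an adjusted p under 0.05, with all 3 tumours beyond the other 9 and a mean RPKM of at least 5 on the higher side. XIST, Y-linked genes, mitochondrially encoded genes and clone-based names were left out of that rule. The 10 genes of largest F, up to 2 highest and 2 lowest of each pair, members of called lists and the genes of a line identity list are named as well.

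The method was tested on simulated data shaped like SCP32 against the other 3 subclones, over 12430 genes. Changes were placed in genes with a mean log2 RPKM above 2. At an adjusted p under 0.05 alone, without the limit on the log2 difference, 78% of genes changed by 0.5 were called. Of those changed by 1, 2 or 3, 100% were called. Calls of unchanged genes were 5% of all calls, and 1 list besides the shifted list was called. The simulated noise was independent between genes, so it does not show how the list test acts on correlated genes. The groups, tests, gene lists, naming rule and 25 alternative settings were fixed before the data were examined. These cover the pseudocount, the filter, the scaling, the trend, moderation and weights, a replicate block, a host marker covariate, the correlation in camera, and leaving out each of the 12 tumours. Another 3 alternatives were chosen after seeing the data: the scores with a shared constant, log2(TPM + 1) rebuilt from the RPKM, and a floor at RPKM 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used for the scale and the plots.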

Results

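Transcript levels were measured by bulk RNA sequencing in 12 tumours grown from 4 subclonal populations of MDA-MB-468, a triple-negative breast cancer line with basal features and very high EGFR. The populations are SCP01, SCP03, SCP29 and SCP32, with 3 mammary gland xenografts each (A, B and C), and the series asks how far tumours of different subclones differ in their transcripts. Estimated library sizes ran from 13.67 M reads (SCP03 B) to 30.54 M (SCP03 A), and between 11673 and 11981 genes per tumour lay above the floor of RPKM 1. Levels are log2 RPKM as mean ± SD of 3 tumours, and differences are log2 ± SE with limma's adjusted p. Where the lower side of a difference includes tumours at the floor, its size is a lower bound. The labels give separate tumours, and p-values measure the spread between these tumours.

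Each subclone kept a transcript profile of its own across its 3 tumours. SCP01 tumours had high LBP, CRISP3 and mammaglobin A and LDHB at the floor, SCP03 tumours high KIT, CCL2 and vimentin, SCP29 tumours high interferon-stimulated genes, and SCP32 tumours high AQP5 and PRAME with low interferon-stimulated genes and lower EGFR. Of 12430 genes tested, 7503 (60.4%) differed among the 4 subclones. Subclone accounted for 75.8% of the variance, against 27.3% by chance and 70.4% in the highest other partition (exact permutation p = 6.5e-05, the smallest that 15400 partitions can give). Correlation across genes, which are not independent replicates, was 0.9718 to 0.9917 for the 12 pairs of tumours of the same subclone and 0.9193 to 0.9776 for the 54 pairs of different subclones. SCP03 and SCP29 lay closest, with a root mean square log2 difference of 0.343 between their means, and SCP01 and SCP32 farthest apart, with 0.628. The median SD of a gene among tumours was 0.107 in SCP01, 0.153 in SCP03, 0.150 in SCP29 and 0.123 in SCP32.

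**Figure D1:**
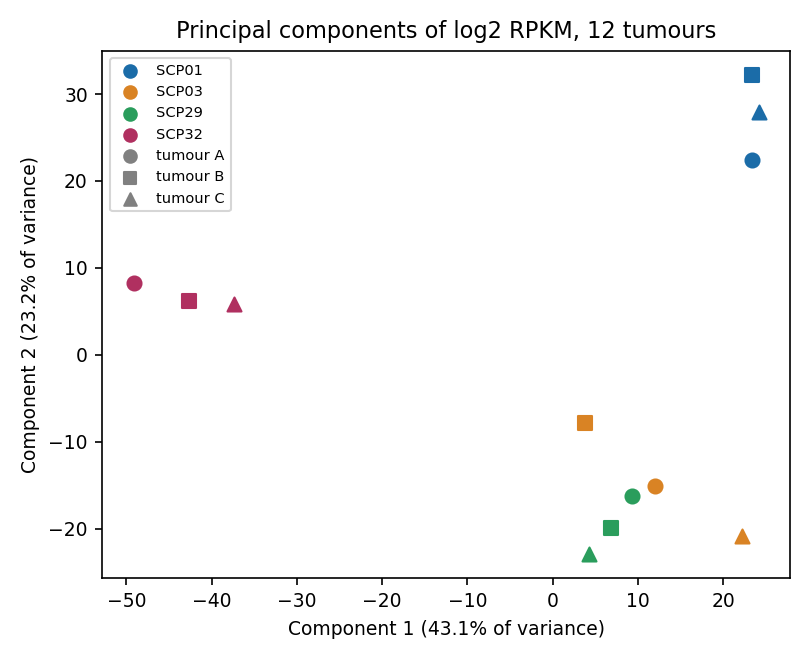
Principal components 1 and 2 of log2 RPKM over the tested genes, holding 43.1% and 23.2% of the variance; each point is a tumour, coloured by subclone with a marker shape per letter. The 3 SCP32 tumours sit apart on component 1 and the 3 SCP01 tumours on component 2, while SCP03 and SCP29 lie close together.

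The genes with the largest F values differed in how they were spread over the subclones. CLEC7A, the beta-glucan receptor dectin-1, was at 3.16 ± 0.09, 3.01 ± 0.04 and 2.98 ± 0.12 in SCP01, SCP03 and SCP29 and at the floor in all 3 SCP32 tumours (F = 525.8, adjusted p = 5.31e-09). KIT, the stem cell factor receptor, was at 3.73 ± 0.09 in SCP01, 4.21 ± 0.31 in SCP03, 1.61 ± 0.16 in SCP32 and 0.08 ± 0.14 in SCP29. JPH2, a junctional membrane protein, decreased stepwise from 3.52 ± 0.07 in SCP01 through 3.16 ± 0.08 in SCP03 and 2.50 ± 0.11 in SCP29 to 1.55 ± 0.01 in SCP32 (F = 183, adjusted p = 1.07e-07). The endothelin-converting enzyme ECE1 was at 4.37 to 4.54 in SCP01, SCP03 and SCP29 and at 2.69 ± 0.09 in SCP32. CASP14, AQP5, LDHB, GLYATL2, TMOD1 and IFI44 complete the 10 and are described with their subclones.

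Genes that define the line were checked in all tumours. RB1 and SMAD4, tumour suppressors this line is known to have lost, were listed at 0 in all 12 tumours. EGFR was at 8.97 ± 0.01 in SCP01, 8.82 ± 0.06 in SCP03, 8.78 ± 0.10 in SCP29 and 7.86 ± 0.19 in SCP32. The luminal keratin KRT8 did not pass the F test (adjusted p = 0.128). Vimentin (VIM), a mesenchymal intermediate filament, was highest in SCP03 at 7.28 ± 0.15, and E-cadherin (CDH1) ran from 4.99 ± 0.10 in SCP01 to 4.07 ± 0.10 in SCP32. The estrogen receptor ESR1 was at 0.75 ± 0.19 in SCP03, 0.37 ± 0.12 in SCP01 and 0.35 ± 0.31 in SCP29 and at the floor in SCP32, and PGR was not found among the gene symbols of the table. ERBB2 was low, at 2.20 ± 0.03 in SCP03 to 2.79 ± 0.18 in SCP01. The basal keratin KRT5 was at 5.44 ± 0.27 in SCP32 and 6.26 ± 0.50 to 6.86 ± 0.53 elsewhere, a fall of -1.11 ± 0.25 in SCP32 (adjusted p = 0.00299) whose call was lost with a host marker covariate although most of the difference stayed (-0.88 ± 0.32, adjusted p = 0.0516). KRT18, a luminal keratin, rose by 0.50 ± 0.09 in SCP32 (adjusted p = 0.000717).

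SCP01 tumours had the highest levels of LBP, CRISP3 and several secretoglobins, while LDHB was at the floor. The fixed list of luminal progenitor and secretory mammary genes was not called in SCP01 (2 of 16 rose and 4 fell; camera adjusted p = 0.623). LBP, the lipopolysaccharide-binding protein, was at 5.91 ± 0.19 in SCP01, 2.57 ± 0.64 in SCP03, 0.35 ± 0.60 in SCP29 and at the floor in SCP32, a difference of 4.94 ± 0.25 from the other 3 (adjusted p = 1e-07). The secreted protein CRISP3 was 4.89 ± 0.48 higher (adjusted p = 1.35e-05). Mammaglobin A (SCGB2A2) was at 7.46 ± 0.35 and 4.51 ± 0.54 higher, and its relatives SCGB1D2 and SCGB2A1 were 3.61 ± 0.27 and 3.45 ± 0.33 higher. The breast epithelial mucin MUCL1 was at 4.08 ± 0.48, with all SCP03 and SCP32 tumours at the floor, the glycoprotein CHI3L1 at 3.73 ± 0.30, with all SCP29 and SCP32 tumours at the floor, and the sweat gland peptide dermcidin (DCD) at 4.31 ± 0.70. GLYATL2, a glycine acyltransferase, and CASP14, a caspase of keratinocyte cornification, were 3.31 ± 0.15 and 3.07 ± 0.16 higher. In the other direction, lactate dehydrogenase B (LDHB) was at the floor in all 3 SCP01 tumours and at 3.53 ± 0.66, 4.23 ± 0.23 and 5.90 ± 0.20 in SCP03, SCP29 and SCP32 (adjusted p = 3.98e-08). TMEM100 and CPPED1 were also at the floor in SCP01. ANGPTL4, an inhibitor of lipoprotein lipase, fell by 2.69 ± 0.23 and the kallikrein KLK10 by -2.55 ± 0.21. WFDC2 was lower by -2.17 ± 0.24 and the matrix protease MMP7 by -1.91 ± 0.12. TCEAL8, PLEKHB1 and the pseudogene TCAM1P were lower by -2.54 ± 0.18, -2.44 ± 0.14 and -1.92 ± 0.15. In all, 389 genes differed, 243 higher and 146 lower in SCP01.

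Hypoxia-responsive genes were higher in SCP01, while interferon, antigen presentation and DNA replication genes were lower. Of 30 measured hypoxia genes, 18 rose, 2 (SLC2A3 and ANGPTL4) fell and 10 were not called (21 rose and 2 fell adjusted over the list alone), with a median of 0.41. The prolyl hydroxylase EGLN3 rose by 1.11 ± 0.08 and the growth factor VEGFA by 1.18 ± 0.16, and ANKRD37 was above the floor only in the 3 SCP01 tumours. The list mean was 4.35, 4.36 and 4.47 in SCP01 A, B and C, and SCP29 A reached 4.47 as well. Camera's adjusted p for the list was 0.00016, and adjusted p = 0.787 with an estimated correlation. Among 34 type I interferon response genes 25 fell, 0 rose and 9 were not called (27 fell adjusted over the list alone; median -0.62; camera adjusted p = 1.86e-08, adjusted p = 0.787 with an estimated correlation). IFI27 fell by 1.49 ± 0.16, the tetherin gene BST2 by -0.95 ± 0.11 and IFI44 by -0.83 ± 0.09. The list mean was lower still in SCP32 (2.44) than in SCP01 (2.85). For antigen presentation by MHC class I, 11 of 17 genes fell, 0 rose and 6 were not called (12 fell adjusted over the list alone; camera adjusted p = 0.00124, adjusted p = 0.784 with an estimated correlation), with B2M lower by -0.72 ± 0.10 and the immunoproteasome gene PSMB8 by -0.54 ± 0.08. Host markers differed in SCP01 as well: 3 of 5 macrophage and leukocyte markers (CORO1A, CD14 and ITGB2) fell and 1 (CSF1R) rose, and 3 of 5 mural markers (ACTA2, TAGLN and NOTCH3) rose and 1 (MCAM) fell. Of 11 fibroblast and collagen markers 2 (FBLN1 and C1S) rose and 2 (COL1A1 and FBN1) fell. In addition 2 of 3 adipocyte markers (PPARG and SLC2A4) rose and 1 of 4 muscle markers (TNNI2) fell. In the DNA replication list 14 of 29 genes fell, 1 (the polymerase gene POLA1, 0.57 ± 0.09) rose and 14 were not called, with the same counts adjusted over the list alone. The sliding clamp PCNA fell by 0.92 ± 0.09, E2F1 by -0.78 ± 0.07 and the helicase gene MCM2 by -0.43 ± 0.07 (camera adjusted p = 0.000565, adjusted p = 0.784 with an estimated correlation).

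Hormone receptor and luminal mature genes were also higher in SCP01: 7 of 12 rose, 0 fell and 5 were not called, the same adjusted over the list alone (median 0.35; camera adjusted p = 0.00608, adjusted p = 0.787 with an estimated correlation). The luminal transcription factors FOXA1 and SPDEF rose by 2.05 ± 0.19 and 1.59 ± 0.21, and XBP1 by 0.68 ± 0.08, while ESR1, at 0.37 ± 0.12 in SCP01, was not called. Cancer-testis antigens were lower, with 4 of 6 fallen, 0 risen and 2 not called (5 fell adjusted over the list alone; camera adjusted p = 0.00126, adjusted p = 0.784 with an estimated correlation). MAGEA12 fell by 0.94 ± 0.11 and CT83 by -0.86 ± 0.11. PRAME counts among the lower genes because of its level in SCP32, since it was at the floor in SCP01, SCP03 and SCP29 alike. Reads of MAGEA3 and MAGEA6, of the HLA genes and of the KRT6 genes may be shared among close copies, so their single values are uncertain.

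**Figure D2:**
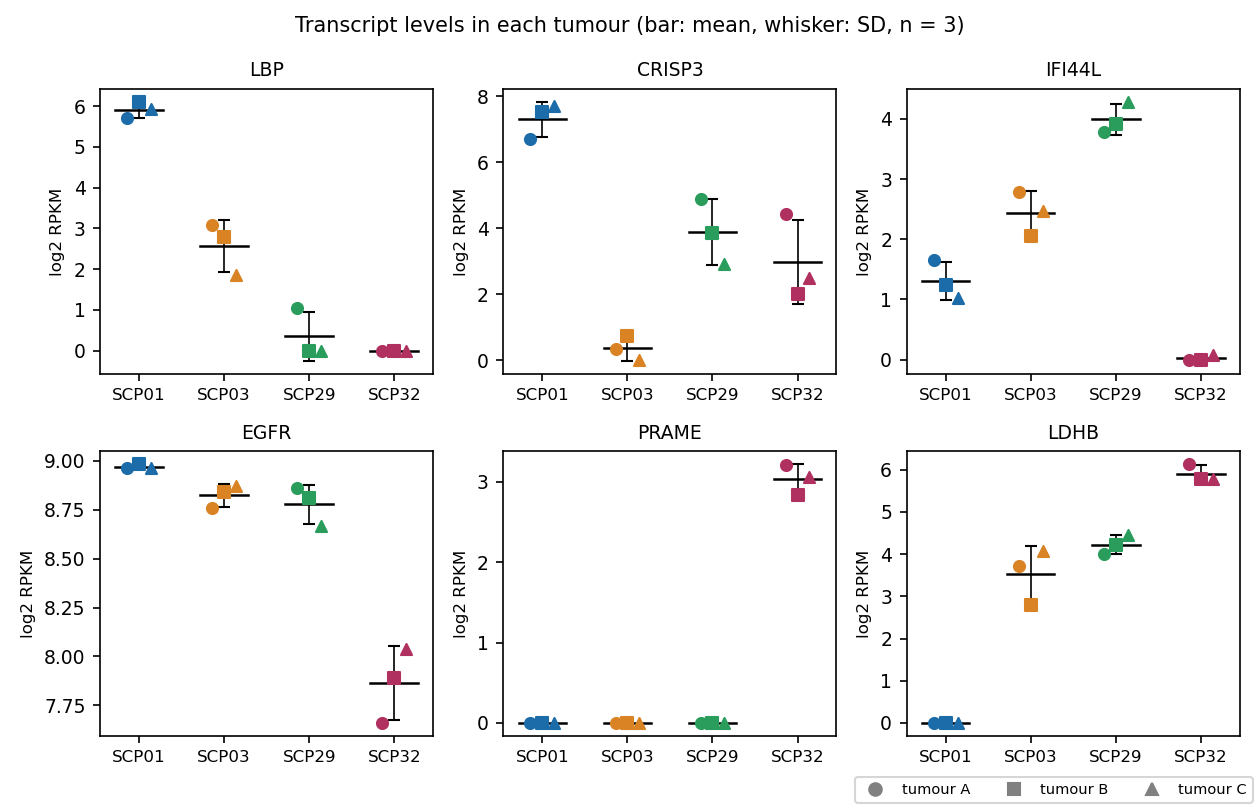
Levels of 6 genes (log2 RPKM, vertical axis) in each tumour by subclone (horizontal axis); points are tumours, bars the mean and whiskers the SD of 3. LBP and CRISP3 are highest in SCP01, where LDHB is at 0 in all tumours; IFI44L is highest in SCP29, EGFR is lowest in SCP32, and PRAME is above 0 in SCP32 alone.

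SCP03 tumours carried more CCL2, KIT and vimentin and had lower ALDH1A1, GABRP and CRISP3. The monocyte chemokine CCL2 was at 4.54 ± 0.44 in SCP03, 3.58 ± 0.03 in SCP01, 1.43 ± 1.32 in SCP29 and at the floor in SCP32, a difference of 2.87 ± 0.38 (adjusted p = 0.000407). KIT was 2.41 ± 0.12 higher (adjusted p = 5.48e-07), the AP-1 factor FOSL1 2.01 ± 0.20, the histone deacetylase HDAC9 1.71 ± 0.15, the intermediate filament gene SYNM 1.62 ± 0.15, the interferon-inducible chemokine CXCL10 1.45 ± 0.18 and VIM 1.06 ± 0.08 (adjusted p = 1.17e-05). PPP1R14C, RASSF2, C1QTNF1 and DOCK11 were higher by 1.64 ± 0.19, 1.49 ± 0.15, 1.43 ± 0.29 and 1.39 ± 0.13. Aldehyde dehydrogenase ALDH1A1 was at 0.53 ± 0.47 against 3.59 ± 0.50, 4.51 ± 0.76 and 4.93 ± 0.25 in SCP01, SCP29 and SCP32, a difference of -3.82 ± 0.29 (adjusted p = 1.1e-05). CRISP3 was lower by -4.36 ± 0.48 and GABRP, a GABA receptor subunit, by -3.57 ± 0.33. FBP1, the gluconeogenic fructose bisphosphatase, was lower by -2.23 ± 0.19, PLXDC2 by -2.40 ± 0.14, SLC12A7 by -1.83 ± 0.20, KCTD15 by -1.77 ± 0.16, OLFM4 by -1.53 ± 0.15 and ARMCX5 by -1.47 ± 0.10, and CLCA2 was at the floor in all 3 SCP03 tumours. In all, 178 genes differed, 61 higher and 117 lower, and 275 did without tumour SCP03 B. That tumour stood apart from SCP03 A and SCP03 C in the mean of the host markers (2.215 against 1.679 and 1.768) and of the ribosomal protein genes (6.63 against 6.02 and 5.80).

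Mitosis genes rose together in SCP03: 18 of 29 rose, 0 fell and 11 were not called (23 rose and 1 fell adjusted over the list alone; median 0.32; camera adjusted p = 5.29e-08, adjusted p = 0.787 with an estimated correlation). The kinesin KIF2C rose by 0.47 ± 0.07, the kinetochore gene CENPF by 0.55 ± 0.09 and CDC20 by 0.38 ± 0.08, while MKI67 was at 4.53 in SCP03 and 4.23 to 4.37 elsewhere and was not called. Type I interferon response genes were intermediate, with 15 of 34 risen, 0 fallen and 19 not called (18 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.18e-06, adjusted p = 0.815 with an estimated correlation). The antiviral GTPase MX1 rose by 0.73 ± 0.11 and OASL by 1.18 ± 0.19. NF-kB cytokines and chemokines gave 9 of 23 risen, 3 fallen (CCL20, CCL22 and CX3CL1) and 11 not called (10 rose and 3 fell adjusted over the list alone), with CXCL16 0.68 ± 0.09 higher and CCL22 -1.64 ± 0.21. Its camera adjusted p was 0.00565, and adjusted p = 0.855 with an estimated correlation. The call of NF-kB cytokines and chemokines was lost without SCP03 A (adjusted p = 0.0699) and with genes of mean RPKM of at least 5 only (adjusted p = 0.0502). SCP03 B did not share the rise: the list mean was 3.09 there, 3.72 in SCP03 A, 3.67 in SCP03 C and 3.22 to 3.32 in SCP01.

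Squamous, luminal, ATF4 and cancer-testis genes were lower in SCP03 by group mean. SCP03 B reached the tumours of another subclone in 3 of these lists. Its squamous mean was 3.88 (SCP03 A 3.48, SCP03 C 2.98), against 3.81 to 3.97 in SCP01. The luminal mature mean was 2.74 (2.58 and 2.26), against 2.66 to 2.74 in SCP29. For ATF4 genes it was 4.77 (4.59 and 4.38), against 4.68 to 4.78 in SCP32. In the squamous differentiation and keratinisation list 8 of 16 fell, 0 rose and 8 were not called, also adjusted over the list alone (median -0.72; camera adjusted p = 0.00016, adjusted p = 0.784 with an estimated correlation). The kallikreins KLK5, KLK6, KLK7 and KLK8, members of a single gene family, were among the 8 that fell. KLK6 fell by 1.08 ± 0.14, and cystatin A (CSTA) and KLK8 were at the floor in all SCP03 tumours. KLK6 and KLK8 were no higher in SCP01, with KLK6 at 2.16 ± 0.33 there and 2.18 ± 0.14 in SCP03 and KLK8 at the floor in both, so their difference rests on SCP29 and SCP32. Luminal mature genes fell in 8 of 12 cases, with 1 risen (ESR1) and 3 not called, also adjusted over the list alone (camera adjusted p = 0.0022, adjusted p = 0.787 with an estimated correlation); GATA3 fell by 0.77 ± 0.15 and MLPH by -0.59 ± 0.10. The rise of ESR1 (0.51 ± 0.12) was lost without SCP03 A (adjusted p = 0.0716). Among genes of the ATF4 amino acid response 8 of 28 fell, 1 (ATF3) rose and 19 were not called (11 fell and 1 rose adjusted over the list alone). Asparagine synthetase (ASNS) fell by 0.65 ± 0.10 and WARS by -0.59 ± 0.07; camera's adjusted p was 0.00257, adjusted p = 0.855 with an estimated correlation, and the call on the amino acid response of ATF4 was lost without SCP03 C (adjusted p = 0.083). Cancer-testis antigens fell in 5 of 6 cases, with 0 risen and 1 not called (6 fell adjusted over the list alone; camera adjusted p = 0.000209, adjusted p = 0.784 with an estimated correlation), MAGEA6 by -0.41 ± 0.08. Their mean was 3.72 in SCP03, 3.63 in SCP01, 4.07 in SCP29 and 5.01 in SCP32, so SCP03 was not lower than SCP01 and the difference rests mostly on SCP32. Of 40 cytosolic ribosomal proteins 1 fell (RPL10, adjusted p = 0.0497), 0 rose and 39 were not called, and 0 passed adjusted over the list alone. The list mean was 6.15 in SCP03 and 6.17 in SCP01. Camera gave an adjusted p of 0.00522 for the cytosolic ribosomal proteins, adjusted p = 0.868 with an estimated correlation, and the call was lost without SCP03 A (adjusted p = 0.117) or SCP03 C (adjusted p = 0.538).

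SCP29 tumours carried a broad rise of interferon-stimulated genes and had low KIT. Of 34 type I interferon response genes, 33 rose, 0 fell and 1 (ISG20) was not called, with the same counts adjusted over the list alone and a median of 1.38. ISG15, a ubiquitin-like antiviral protein, was at 9.40 ± 0.11 in SCP29 against 6.73 ± 0.50, 7.64 ± 0.24 and 6.66 ± 0.12 in SCP01, SCP03 and SCP32, a difference of 2.39 ± 0.17 (adjusted p = 6.47e-06). IFI44L was 2.73 ± 0.16 higher (adjusted p = 1.96e-06), IFIT1 2.32 ± 0.20, IFIT3 2.22 ± 0.19, IFI6 2.20 ± 0.19, IFIT2 2.14 ± 0.12, XAF1 2.00 ± 0.19 and IFI44 1.57 ± 0.09. Camera gave an adjusted p of 1.78e-33, and adjusted p = 0.411 with an estimated correlation. For antigen presentation by MHC class I, 14 of 17 genes rose, 0 fell and 3 (TAPBP, CALR and PDIA3) were not called, also adjusted over the list alone (median 0.67; camera adjusted p = 7.91e-10, adjusted p = 0.411 with an estimated correlation). The peptide transporter TAP1 rose by 0.86 ± 0.12, the immunoproteasome gene PSMB9 by 0.92 ± 0.10, the peptidase ERAP1 by 0.61 ± 0.07 and B2M by 0.72 ± 0.10.

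Outside the interferon genes, FGFBP2, a secreted protein, was 2.81 ± 0.18 higher in SCP29, TMEM156 1.94 ± 0.19 and the calcium-binding protein S100A2 1.85 ± 0.18. KIT fell by 3.11 ± 0.12 (adjusted p = 8.05e-08), with 2 of 3 SCP29 tumours at the floor, the mucosal chemokine CXCL17 by -3.04 ± 0.30, SPINK8 by -2.26 ± 0.24, the acid phosphatase ACP5 by -2.16 ± 0.13, CYP1B1 by -2.15 ± 0.25 and mesothelin (MSLN) by -2.10 ± 0.21. VSNL1, malic enzyme ME1, GPNMB and SUN3 were lower by -1.90 ± 0.17, -1.65 ± 0.11, -1.53 ± 0.15 and -1.46 ± 0.18. In all, 184 genes differed, 91 higher and 93 lower.

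The ATF4, the EGFR and MAPK feedback and the basal lists were modestly higher in SCP29 than in the mean of the others. Of 28 ATF4 amino acid response genes 12 rose, 2 (CEBPB and VLDLR) fell and 14 were not called (14 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.00161, adjusted p = 0.855 with an estimated correlation), with the serine synthesis gene PSAT1 0.59 ± 0.08 and CBS 0.57 ± 0.10 higher. Of 23 EGFR and MAPK feedback and ligands genes 6 rose, 1 (DUSP6) fell and 16, EGFR itself among them, were not called, also adjusted over the list alone. SPRY2, a feedback inhibitor, rose by 0.71 ± 0.09 and the receptor EPHA4 by 0.82 ± 0.10. The list mean was 3.66 in SCP29, 3.54 in SCP03, 3.50 in SCP01 and 3.19 in SCP32, so the largest gap was to SCP32. Camera's adjusted p was 0.00931, adjusted p = 0.784 with an estimated correlation, and the call on EGFR and MAPK feedback and ligands was lost with array quality weights (adjusted p = 0.0709). In the basal keratinocyte-type list 5 of 20 rose, 1 (TP63) fell and 14 were not called (6 rose and 1 fell adjusted over the list alone), KRT14 by 1.37 ± 0.25 and the hemidesmosome gene ITGB4 by 0.81 ± 0.12. The list mean was 3.87 in SCP29 and SCP03 alike. Its camera adjusted p was 0.0177, adjusted p = 0.855 with an estimated correlation, and the basal keratinocyte-type call was lost without SCP29 A (adjusted p = 0.26), with a host marker covariate (adjusted p = 0.0582) and on log2(TPM + 1) (adjusted p = 0.0581). Host fibroblast and collagen markers had a median of -0.48 with 1 of 11 (the complement protease C1S) fallen, 0 risen and 10 not called, also adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.796 with an estimated correlation). That host fibroblast and collagen call was lost without SCP29 C (adjusted p = 0.0587), with array quality weights (adjusted p = 0.176), with the host marker covariate (adjusted p = 0.4) and with a floor at RPKM 2 (adjusted p = 0.161), where C1S reached an adjusted p of 0.05.

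**Figure D3:**
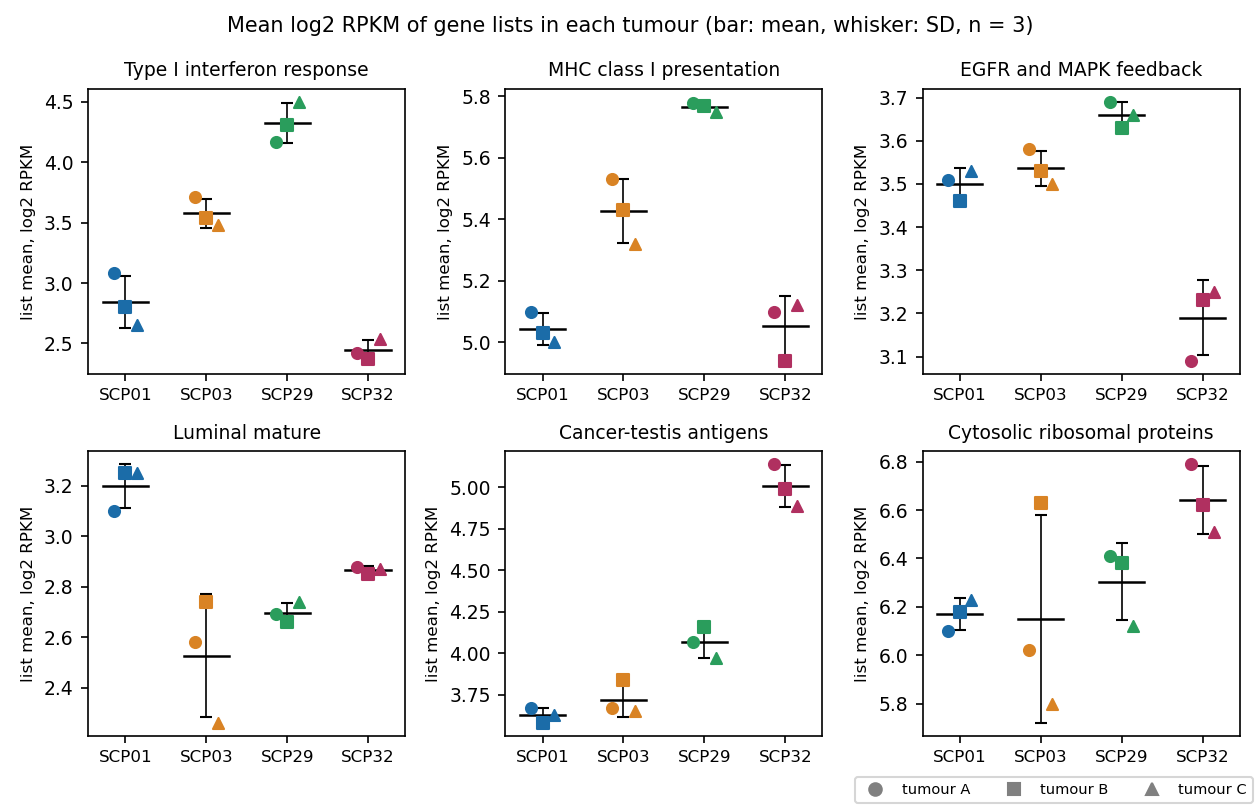
Mean log2 RPKM (vertical axis) over the tested members of 6 gene lists in each tumour by subclone (horizontal axis); points are tumours, bars the mean and whiskers the SD of 3. The interferon list means are 2.85 in SCP01, 3.58 in SCP03, 4.33 in SCP29 and 2.44 in SCP32, and the cancer-testis means are highest in SCP32.

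SCP32 tumours differed most from the rest. The water channel AQP5 was at 6.22 ± 0.34 against 0.69 ± 0.42, 2.67 ± 0.46 and 1.19 ± 0.14 in SCP01, SCP03 and SCP29, a difference of 4.71 ± 0.21 (adjusted p = 2.68e-08). PRAME, a cancer-testis antigen, was at 3.04 ± 0.19 in SCP32 and at the floor in the 9 other tumours (adjusted p = 5.68e-10), as was SCGB3A1, a secretoglobin at 4.19, 2.41 and 2.14 in SCP32 A, B and C. The chemokine CXCL17 was 3.61 ± 0.30 higher, LDHB 3.31 ± 0.20, CCL22, another chemokine, 2.99 ± 0.21, TCEAL8 2.84 ± 0.18, SYT8 2.81 ± 0.14 and the troponin gene TNNC1 2.77 ± 0.24. Host muscle markers moved with TNNC1: 3 of 4 (ACTA1, TNNI2 and CKM) rose in SCP32. TGFBI, a matrix protein induced by TGF-beta, was at 1.61 ± 0.17 against 5.51 ± 0.17, 5.08 ± 0.24 and 5.35 ± 0.55, a difference of -3.71 ± 0.18 (adjusted p = 5.73e-08). SCGB2A2 was lower by -4.52 ± 0.54, CASP14 by -3.21 ± 0.16, FOSL1 by -2.54 ± 0.20, the actin-capping protein TMOD1 by -2.42 ± 0.11, the death ligand TNFSF10 by -2.37 ± 0.14 and GLYATL2 by -2.34 ± 0.15. In all, 679 genes differed, 378 higher and 301 lower; the share of higher genes was 55.7%, and 41.5% when mitochondrial and the 50 most abundant genes were left out of the scaling.

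Most interferon genes that were high in SCP29 were low in SCP32. Of 34 type I interferon response genes 28 fell, 0 rose and 6 (ISG20, MX2, IFI27, IFI35, IRF7 and BST2) were not called (30 fell and 1 rose adjusted over the list alone), with a median of -1.13. IFIT3 fell by 2.62 ± 0.19, IFI44L by -2.55 ± 0.16, MX1 by -1.91 ± 0.11 and IFI44 by -1.28 ± 0.09, and IFIT2 was at the floor in all SCP32 tumours. Camera's adjusted p was 1.4e-12, and adjusted p = 0.784 with an estimated correlation. For antigen presentation by MHC class I, 7 of 17 genes fell, 0 rose and 10 were not called, also adjusted over the list alone; TAP2 fell by 1.10 ± 0.14 and PSMB9 by -0.84 ± 0.10. The list mean was 5.05 in SCP32 and 5.04 in SCP01, against 5.42 in SCP03 and 5.77 in SCP29, so SCP32 was not lower than SCP01. Its camera adjusted p was 0.0203, adjusted p = 0.796 with an estimated correlation, and the antigen presentation by MHC class I call was lost without SCP32 B (adjusted p = 0.0685). Of 30 hypoxia genes 16 fell, 2 (SLC2A3 and TMEM45A) rose and 12 were not called (18 fell and 2 rose adjusted over the list alone; median -0.34; camera adjusted p = 0.00608, adjusted p = 0.855 with an estimated correlation), with EGLN3 lower by -1.02 ± 0.08 and AK4 by -0.74 ± 0.08.

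EGFR and several of its feedback genes were lower in SCP32. EGFR fell by 0.99 ± 0.09 (adjusted p = 4.43e-06), the feedback inhibitor ERRFI1 by -1.10 ± 0.09 and cyclin D1 (CCND1) by -0.92 ± 0.08. Of 23 EGFR and MAPK feedback and ligands genes 12 fell, 4 (DUSP6, SPRY1, ETV4 and EPHA4) rose and 7 were not called, also adjusted over the list alone. Camera's adjusted p was 0.049, and adjusted p = 0.787 with an estimated correlation. This call of EGFR and MAPK feedback and ligands was lost in 11 of 27 other settings, with an adjusted p of up to 0.09, among them the settings without SCP32 A (adjusted p = 0.09), SCP03 A (adjusted p = 0.0509) and SCP29 C (adjusted p = 0.0587).

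Squamous, cancer-testis, respiratory and ribosomal protein genes were higher in SCP32. Of 16 squamous differentiation genes 10 rose, 0 fell and 6 were not called, also adjusted over the list alone (median 0.94; camera adjusted p = 0.0022, adjusted p = 0.787 with an estimated correlation), among them CSTA by 2.11 ± 0.19 and the kallikreins KLK6 by 1.43 ± 0.14 and KLK5 by 1.26 ± 0.12. The kallikreins KLK5, KLK6, KLK7, KLK8 and KLK10 were among these 10. Much of the count is thus a single gene family, whose members may not move independently. The kallikreins were not particular to SCP32, since the same genes rose in SCP29 too, KLK5 by 0.70 ± 0.12. KLK10 was at 3.57 ± 0.28 in SCP29 and 3.44 ± 0.04 in SCP32. In SCP29 the squamous list was not called (camera adjusted p = 0.341). Each of the 6 cancer-testis antigens measured rose, also adjusted over the list alone, MAGEA12 by 1.13 ± 0.11 and CT83 by 0.94 ± 0.11 (camera adjusted p = 0.000163, adjusted p = 0.784 with an estimated correlation). In the nuclear-encoded oxidative phosphorylation list 24 of 42 rose, 1 (SDHB, -1.01 ± 0.11) fell and 17 were not called (25 rose and 1 fell adjusted over the list alone; median 0.33), with NDUFA3 higher by 0.87 ± 0.10 and UQCRB by 0.92 ± 0.14 (camera adjusted p = 0.00172, adjusted p = 0.855 with an estimated correlation). Of 40 cytosolic ribosomal proteins 21 rose, 1 (RPL22, -0.48 ± 0.09) fell and 18 were not called, also adjusted over the list alone (median 0.40; camera adjusted p = 0.000611, adjusted p = 0.868 with an estimated correlation), with RPS20 higher by 0.92 ± 0.13 and RPLP1 by 0.81 ± 0.13. Host markers moved as well: 5 of 11 fibroblast and collagen markers (COL1A1, COL1A2, COL3A1, FBN1 and BGN) rose and 2 (FBLN1 and C1S) fell in SCP32. In addition 3 of 4 muscle markers and 2 of 5 macrophage and leukocyte markers (CD14 and ITGB2) rose, and 1 mural marker (TAGLN) rose and 2 (NOTCH3 and MYLK) fell. With a host marker covariate both calls were lost, as the median (± SD over members) went from 0.33 ± 0.34 to 0.19 ± 0.33 for oxidative phosphorylation, nuclear-encoded (adjusted p = 0.0938) and from 0.40 ± 0.29 to 0.14 ± 0.29 for cytosolic ribosomal proteins (adjusted p = 0.289). That shift rested on SCP03 B, without which the covariate left medians of 0.37 and 0.43.

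Comparing subclones in pairs, SCP01 and SCP32 differed in the most genes, 1058 (533 higher and 525 lower in SCP01), and SCP03 and SCP29 in the fewest, 186 (89 and 97). SCP03 and SCP32 differed in 824 (358 and 466), SCP29 and SCP32 in 740 (346 and 394), SCP01 and SCP29 in 513 (292 and 221) and SCP01 and SCP03 in 416 (265 and 151), with the first number of each bracket for genes higher in the subclone named first. Between SCP01 and SCP03 the extremes were CRISP3 (6.93 ± 0.58) and SCGB2A1 (4.63 ± 0.40), higher in SCP01, and TCAM1P (-2.44 ± 0.18). LBP (5.56 ± 0.31) and DCD (3.98 ± 0.32) were higher in SCP01 than in SCP29, and GABRP was lower (-3.64 ± 0.41). SCGB2A2 (6.77 ± 0.66) was higher in SCP01 than in SCP32, where LBP was at the floor, and AQP5 was lower (-5.53 ± 0.25). LDHB, at the floor in SCP01, was the lowest gene of SCP01 against each other subclone. KIT (4.14 ± 0.15) and CCL2 (3.11 ± 0.47) were higher in SCP03 than in SCP29, and GABRP (-4.38 ± 0.41) and ALDH1A1 (-3.98 ± 0.35) were lower. TGFBI (3.47 ± 0.22) was higher in SCP03 than in SCP32, where CCL2 was at the floor, while GABRP (-5.59 ± 0.41) was lower. SCGB2A2 (4.55 ± 0.66) and IFI44L (3.97 ± 0.20) were higher in SCP29 than in SCP32, and AQP5 (-5.03 ± 0.25) and CXCL17 (-4.99 ± 0.37) were lower. With mitochondrial and the 50 most abundant genes left out of the scaling, the share of higher genes moved from 50.4% to 65.8% for SCP01 against SCP32 and from 46.8% to 57.3% for SCP29 against SCP32.

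Lists that did not pass camera in any of the 4 subclones included the epithelial adhesion, mesenchymal, luminal progenitor, glycolysis, cholesterol, fatty acid, unfolded protein, NRF2, TGF-beta, YAP, Notch, Wnt, matrix proteolysis, immediate early, heat shock, mitochondrially encoded, aldehyde dehydrogenase and stemness, drug efflux, host macrophage, host mural and line identity lists. Lists of MHC class II, neural, host endothelium, host adipocyte, host muscle and host erythroid genes had fewer than 5 tested members and were not tested. Camera called 6 lists in SCP01, 8 in SCP03, 6 in SCP29 and 8 in SCP32, while other splits of the same tumours reached 13, 15, 12 and 14. The number of lists called therefore does not exclude chance, and 0 lists were called in each subclone with an estimated correlation.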

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

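Settings that changed the pseudocount, the filter, the floor or the weights moved the numbers of genes called, and 1 other scaling moved their direction. With a pseudocount of 5, 78 genes differed in SCP01, 23 in SCP03, 29 in SCP29 and 120 in SCP32, against 389, 178, 184 and 679. Between pairs that setting gave 72 (SCP01 and SCP03), 96 (SCP01 and SCP29), 207 (SCP01 and SCP32), 25 (SCP03 and SCP29), 161 (SCP03 and SCP32) and 144 (SCP29 and SCP32), against 416, 513, 1058, 186, 824 and 740. Median SDs became 0.058, 0.081, 0.079 and 0.066, against 0.107, 0.153, 0.150 and 0.123; a pseudocount shrinks every log2 difference by construction. Testing only genes with a mean RPKM of at least 5 left fewer genes: 4867 of them differed among the 4 subclones (7503 in the report), 180, 81, 96 and 321 in the subclones, and 180, 235, 505, 89, 388 and 349 in the pairs. Array quality weights gave 11299 genes among the 4 subclones, 287 between SCP03 and SCP29 and 13 lists in SCP03 (8 in the report); the weights ran from 0.287 to 28.5, and how they act on these numbers was not tested. On log2(TPM + 1), 742, 433, 448 and 1208 genes differed in SCP01, SCP03, SCP29 and SCP32 and 290 between SCP03 and SCP29, and ESR1 in SCP29 turned from -0.02 to 0.72 (adjusted p = 0.00438); the cause was not tested. A floor at RPKM 2 gave 254 in SCP01, 102 in SCP03, 122 in SCP29, 270 between SCP01 and SCP03 and 113 between SCP03 and SCP29, as fewer tumours lie above a higher floor. With an estimated inter-gene correlation 0 lists were called in SCP01, 0 in SCP03, 0 in SCP29 and 0 in SCP32, against 6, 8, 6 and 8. Leaving out mitochondrial and the 50 most abundant genes from the scaling moved the share of higher genes from 55.7% to 41.5% in SCP32, from 50.4% to 65.8% between SCP01 and SCP32 and from 46.8% to 57.3% between SCP29 and SCP32; the cause was not tested. Leaving out tumours singly gave 145 to 275 genes for SCP03, the highest without SCP03 B, and median SDs of 0.079 to 0.108 in SCP01, 0.108 to 0.164 in SCP03, 0.103 to 0.174 in SCP29 and 0.083 to 0.124 in SCP32, from fewer samples. A block for the tumour letter gave 7602 genes among the 4 subclones, 389, 178, 182 and 680 in the subclones, 417, 514, 1061, 185, 829 and 750 in the pairs and 6, 10, 7 and 8 lists, and the letters showed no pairing: 3 of 12 tumours correlated best with their own letter. Over named genes and settings, 6435 values stayed the same, 73 became weaker, 45 stronger, 24 moved and 1 reversed.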

Other observations

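Some genes of glucose use rose and others fell within SCP32, which the report does not describe. The glycolysis genes of the next sentences and the single genes after them were chosen after their values were seen. Of 18 glycolysis genes measured, 8 fell in SCP32 and 4 rose. Enolase ENO1 fell by 0.93 ± 0.11 (adjusted p = 3.26e-05), hexokinase HK2 by -0.58 ± 0.08 and lactate dehydrogenase LDHA by -0.38 ± 0.08, whereas the phosphofructokinase PFKM rose by 1.02 ± 0.10 and PGAM1 by 0.45 ± 0.08. Lactate transporters differed as well: SLC16A3 was at 2.08 ± 0.08 in SCP32 and 0.77 ± 0.15 in SCP01, and SLC16A1 was highest in SCP29 at 2.57 ± 0.26. HK2 rose by 0.73 ± 0.08 in SCP01 (adjusted p = 4.58e-05), the subclone with LDHB at the floor. Camera did not call glycolysis in SCP32 (adjusted p = 0.494). The list mean differed among the subclones by exact permutation (adjusted p = 0.00481), from 5.11 in SCP01 to 5.45 in SCP29, with 5.29 in SCP32.

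Some single genes with large differences are not in the report either, and they stand for no tested group. CD44, the hyaluronan receptor, was at 6.65 ± 0.10 in SCP32 and 7.57 to 7.79 elsewhere (adjusted p = 5.22e-07). ELF5, a factor of alveolar differentiation, was at 2.97 ± 0.30 in SCP32 and 0.10 ± 0.13 in SCP01. The membrane protease TMPRSS2 fell by 1.63 ± 0.08 in SCP32 (adjusted p = 5.93e-08), and the protease inhibitor TIMP3 rose by 1.42 ± 0.14. CD14, the receptor partner of LBP, was lowest in SCP01 (-1.48 ± 0.12, adjusted p = 3.67e-06), but it is on the host macrophage and leukocyte list, where CORO1A (-0.85 ± 0.15) and ITGB2 (-0.81 ± 0.12) fell with it, 3 of 5 members in all, and CSF1R rose. The alarmin S100A8 was at 7.61 ± 0.43 in SCP01 and at 4.33 ± 1.90 in SCP03, where its tumours were widely spread.

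Tests chosen only after the result was seen were both tests of the interferon pattern, the tests of host reads and of the SCP32 libraries alone for the ribosomal genes, and the exact permutation tests of list means per tumour. Those permutation tests, over all 15400 partitions, passed for 24 of 37 lists after adjustment, with the type I interferon list at an adjusted p of 0.0024 (p = 6.5e-05, the smallest possible). The cancer-testis, the EGFR and MAPK and the host mural lists had an adjusted p of 0.00361, antigen presentation by MHC class I, squamous and luminal mature genes 0.00412, DNA replication 0.00481, host macrophage markers 0.0199, ATF4 genes 0.0335, and mitosis and hypoxia 0.0372. Lists that camera called in no subclone passed too, among them glycolysis (0.00481), TGF-beta (0.00551), fatty acid, YAP and p53 genes (0.0181 each), Notch and line identity (0.0257 each) and Wnt (0.0267). With 75.8% of the variance of all tested genes between subclones, a pass is not particular to a list. Called lists that did not pass by exact permutation were basal genes (adjusted p = 0.158), NF-kB genes (0.108), oxidative phosphorylation (0.0595), ribosomal proteins (0.15) and host fibroblast markers (0.117).

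Type I interferon genes were high in SCP29, and reads of host cells, scaling or the tumour cells themselves could each account for it. With the mean of host markers as a covariate the median difference was 1.26. That mean was 1.585 to 1.709 in SCP29 and 1.549 to 2.215 in the other tumours, so the covariate had little to remove. These values argue against more host cells in SCP29, as far as the markers capture them. A stronger interferon response within host cells would not show in the markers and remains open. Over 3 other scalings the lowest median was 1.37. These scalings left the median difference of all tested genes at -0.01 to 0.004, far below that of the list, which argues against per-library scaling. Of the 20 fibroblast, endothelial and macrophage markers in that mean, 1 (CD14) rose and 1 (C1S) fell in SCP29, and among mural markers TAGLN fell. A state held by the SCP29 cells remains possible, as does a response to their site that all 3 tumours share, and growing SCP29 cells in culture and reading the same genes could tell these apart.

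Ribosomal protein genes were higher in SCP32, which may come from transcript length, scaling, host reads, a few libraries or a change in the cells. Other protein-coding genes with the same total length of annotated exons had a median of 0.11 against 0.40 for the list. That total, with a median of 3718.5 bases for the ribosomal genes, covers all annotated exons and is not the length of their transcripts. The test therefore cannot decide on transcript length bias, which remains possible. Over 3 other scalings the lowest median of the list was 0.24, which excludes scaling as the whole cause. In the test of the SCP32 libraries alone, 1 tumour of another subclone (SCP03 B, 6.63) lay above the lowest SCP32 tumour (6.51), so these data cannot tell. With the host marker covariate the list median was 0.14, but 0.43 without SCP03 B, so host reads remain open too, and counting reads after sorting them by species could settle their share.

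Shifts of neighbouring genes and the fall of EGFR in SCP32 could share a cause in gene dosage. In SCP32, 1127 of 10692 windows of 51 neighbouring genes lay beyond the limit from 1000 shuffled orders, which excludes a random order of genes. Shuffling also separates neighbours that vary together for other reasons, so this test cannot tell gene dosage from those. The lowest window, on chromosome 1 (order from GENCODE 29 on GRCh38), had a median of -0.86 with 50 of 51 genes lower. In that window this excludes a few genes as the source. With the host marker covariate its median was -0.91, which excludes reads from host cells there as far as these markers capture them. Such shifts were not particular to SCP32, with 838 windows beyond the limit in SCP01, 677 in SCP03 and 1403 in SCP29; the window on chromosome 1 holds ENO1, ERRFI1 and RPL22, of which RPL22 fell while 21 of the 40 ribosomal protein genes rose. The 10 nearest neighbours of EGFR had a median of 0.27, with 3 of them lower, which argues against a lower dosage of a wider region around EGFR. A change limited to EGFR itself cannot be read from neighbours. EGFR-AS1, whose reads may be shared with EGFR, was at -1.52, while SEC61G and LANCL2 were at 0.30 and 0.26. Copy number from DNA of each subclone would test the chromosome 1 run and a change limited to EGFR.

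Chance was tested by redrawing groups of the same sizes from the same tumours, and the counts of genes excluded it. For genes differing among the 4 subclones 1 of 100 splits, the real split, reached 7503, and the highest other gave 2905. For SCP01 2 of 100 splits reached the real 389 (highest other 630), for SCP03 3 reached 178 (632), for SCP29 3 reached 184 (630) and for SCP32 1 reached 679 (22). Each other split as large set apart all 3 tumours of another subclone, a structure of the samples, and the splits that mixed subclones reached at most 57, 58, 14 and 22. Counts of called lists did not exclude chance: 72 of 100 splits reached 6 in SCP01 (highest other 13), 40 reached 8 in SCP03 (15), 71 reached 6 in SCP29 (12) and 37 reached 8 in SCP32 (14). For pairs of subclones 10 splits are too few to tell, with 1 of 10 reaching the real count in each: 416 for SCP01 and SCP03, 513 for SCP01 and SCP29 and 1058 for SCP01 and SCP32 (highest other 0 in each), 186 for SCP03 and SCP29 (2), 824 for SCP03 and SCP32 (1) and 740 for SCP29 and SCP32 (2).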
